A study of Rattus norvegicus with 6 samples.

How the data were processed

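Lung tissue of 3 WT and 3 Tmprss2 KO rats was profiled. Per the labels, total RNA was extracted with TRIzol, messenger RNA was selected with poly-T beads, fragmented and reverse transcribed with random hexamers, and libraries were sequenced as paired 150 base reads on an Illumina platform. The labels name the rats as biological replicates and put all 6 libraries in one batch. Sex, age and litter are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

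Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.2.1, StringTie 2.2.3, featureCounts 2.0.6 and DESeq2 1.42.0 on the build mRatBN7.2; the notes give no roles or settings, and strand handling and the treatment of reads that match several places are not given in the sources used here. The authors deposited raw read counts per gene for 40995 genes. They also deposited FPKM values, which were checked to equal the count divided by gene length and by a library size proportional to a DESeq2-type size factor rather than to the total count. The authors' deposited table of their KO against WT comparison lists 192 genes with log2 fold changes, p-values, and a signal per library, which is the raw count divided by one size factor per library. The 192 raw counts per library in it were identical to those of the count table. Even counts outnumbered odd ones among genes with low counts: in WT replicate 1, 3171 genes had an even count from 2 to 10 and 1641 an odd count from 1 to 9. This pattern arises when both mates of a pair are counted, so counts appear to be reads, and the number of independent fragments is smaller than the counts. Total counts were 76.25% to 83.67% of the clean reads the labels give. Poly-A selection leaves most RNA without a poly-A tail unmeasured, and gene totals do not separate isoforms.

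Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), glmQLFit and glmQLFTest with genotype as the single term, and Benjamini-Hochberg adjustment over 18464 tested genes, with a threshold of 0.05 and no minimum fold. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values use TMM library sizes. Every adjusted p of a gene is from this fit unless another tool is named. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, again with an estimated correlation, and with fry; the adjustment covered the 59 lists with at least 5 tested genes together. Of 1013 symbols in 60 lists fixed before the data were examined, 979 matched the table's gene names, 12 matched through RefSeq symbols or synonyms (assembly GRCr8, used for names alone) and 22 were not matched. Coordinates are those of the deposited table.

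The rule for named genes was set before the data were examined. It takes Tmprss2, then, among genes past the threshold with a mean of at least 1 CPM in the higher group, no overlap between groups and a symbol that is not an identifier, the 8 with the largest fold and the 5 with the smallest p in each direction; 9 genes met it. As fewer than 20 did, 11 more with a symbol that the rule allows were added by smallest p and are said not to pass. Up to 4 members with the smallest p are named for each list described. The same rule, applied without WT replicate 1 after that library was seen to stand apart, gave 24 genes.

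The gene and list tests were tested on simulated data with the real means, library sizes and dispersions and 200 genes changed by known folds. The members of 1 list were shifted 2-fold as well. The 200 genes were drawn among those with higher counts, genes varied independently, and no simulated library stood apart. The shares recovered need not hold for the real data. For the comparison with all 6 libraries, over 18119 simulated genes, 45% of the 2-fold changes and 92% of the 4-fold changes were recovered, and 7.64% of the calls were unchanged genes. For the comparison without WT replicate 1, over 18614 genes, 79% and 100% were recovered, and 7% of the calls were unchanged genes. All 6 libraries were kept as separate samples, as the labels name them. A chi-square of their counts, which counting both mates inflates, was used only to look for a sample counted again and found none: per gene it was 7.52 to 11.2 among KO libraries and between WT replicates 2 and 3, and 138 and 168 for WT replicate 1 against them.

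Alternatives fixed in advance were other normalizations (RLE, upper quartile), DESeq2 1.42.0, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, a robust fit, other filters, protein-coding genes alone, a replicate block, a minimum fold, other windows around Tmprss2, and leaving out each library in turn. After the data were seen, limma-voom with sample quality weights and DESeq2 on unfiltered genes with an absolute log2 fold change of at least 1 were added. No genome sequence was used, so GC content and the edited bases of Tmprss2 were not analysed here.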

Results

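Lung tissue of 6 rats on a Sprague-Dawley background was profiled by mRNA sequencing. The 3 wild-type (WT) rats were compared with 3 rats of a knockout (KO) line made by CRISPR/Cas9 editing of Tmprss2, which encodes a type II transmembrane serine protease of airway and alveolar epithelium that cleaves the entry proteins of several respiratory viruses. No treatment was given, so the comparison asks how the lung transcriptome of the edited line differs from that of WT rats at baseline. Read counts for 40995 genes totalled 33839171, 33033732 and 36895162 in WT replicates 1, 2 and 3 and 29933359, 30514778 and 30155176 in KO replicates 1, 2 and 3. After the filter on low counts, 18464 genes were tested.

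WT replicate 1 stood apart from the other 5 libraries. It lay at -108.6 on the first principal component, which held 59.8% of the variance of log2 CPM (counts per 1e6 counts), while the other 5 lay between 9.09 and 30.6. Its Pearson correlation with the others, across genes, was 0.936 to 0.948, against at least 0.979 among the rest. On the second component, with 15.8% of the variance, WT replicates 2 and 3 lay at -35.9 and -34.0 and the KO libraries between 15.8 and 24.8. The library carried RNA of striated muscle and squamous epithelium. Acta1, the skeletal muscle actin, stood at 5077 CPM in WT replicate 1 and at 0.694 to 2.39 CPM in the other 5 libraries. Krt13 and Krt4, keratins of non-cornifying squamous epithelium, stood at 1339 and 1579 CPM against at most 0.429 and 1.04 CPM elsewhere. Genes of natural killer (NK) cells were lowest in the same library: perforin (Prf1) stood at 9.01 CPM there, at 36.6 and 37.9 CPM in WT replicates 2 and 3, and at 72.3 to 74.9 CPM in the KO libraries. Because of this library, values without WT replicate 1 are given beside each gene group below.

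**Figure D1:**
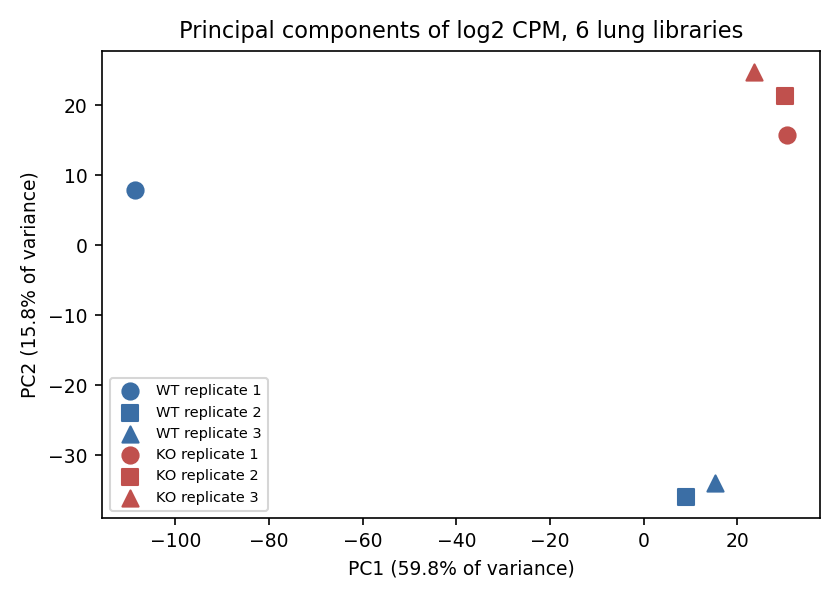
Scores of the 6 lung libraries on the first 2 principal components of log2 CPM over the 18464 tested genes; colour marks genotype and symbol marks replicate. WT replicate 1 lies at -108.6 on the first axis, and the second axis parts WT replicates 2 and 3 from the 3 KO libraries.

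**Figure D2:**
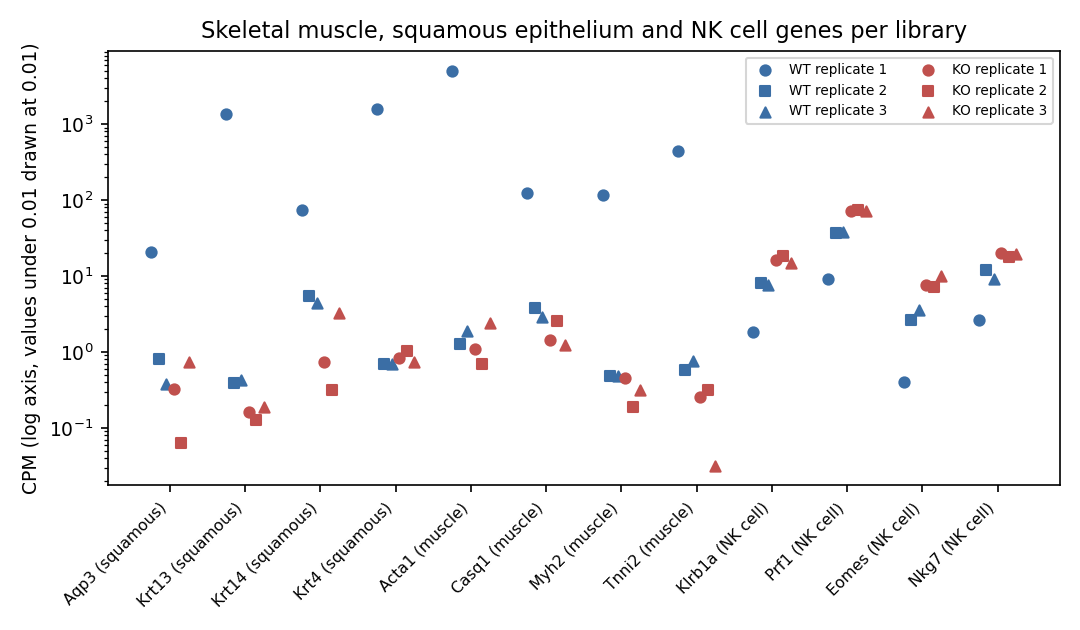
CPM on a log axis of 4 squamous epithelium, 4 skeletal muscle and 4 NK cell genes in each library; colour marks genotype and symbol marks replicate. WT replicate 1 is highest for the muscle and squamous genes, with Acta1 at 5077 CPM, and lowest for the NK cell genes.

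Tmprss2 mRNA was not lost in the KO libraries. Tmprss2 (chromosome 11, 36934306 to 36973779 of mRatBN7.2, minus strand) stood at 50.5, 62.0 and 65.7 CPM in WT replicates 1 to 3 and at 46.1, 56.4 and 47.0 CPM in KO replicates 1 to 3. The means were 59.4 ± 7.93 CPM in WT and 49.8 ± 5.69 CPM in KO (SD, n = 3 each), and the deposited FPKM values averaged 15.5 ± 1.97 and 12.9 ± 1.45. The log2 fold change was -0.25 (SE 0.14, 95% confidence interval -0.58 to 0.07), with an edgeR adjusted p of 0.508. In the fit without WT replicate 1 it was -0.36 (SE 0.09), with an adjusted p of 0.0589. Gene totals do not show a frameshift or a small deletion, so the mRNA level neither checks the genotype labels nor measures the protein.

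Among the 10 genes that passed the test, the largest differences were the near loss of lipocalin 2 and complement C5 from the KO lungs. Larger fold changes, such as those of Krt13 and Acta1, came from WT replicate 1 and did not pass. Lcn2, a siderophore-binding protein of innate immunity, fell from 205 ± 80.0 CPM in WT to 2.91 ± 0.225 CPM in KO (SD, n = 3 each), 70.4-fold lower. C5, the complement component cleaved into C5a and the start of the membrane attack complex, fell from 69.8 ± 10.8 to 2.12 ± 0.0485 CPM, 32.9-fold lower. Their log2 fold changes were -6.14 (SE 0.36, edgeR adjusted p = 0.00356) and -5.04 (SE 0.16, adjusted p = 9.02e-05). C5 passed with any 1 library left out, but Lcn2 did not pass without KO replicate 1, 2 or 3 (edgeR adjusted p 0.0956, 0.0669 and 0.0644), at log2 fold changes of -6.16, -6.08 and -6.18. The pair lie on chromosome 3, Lcn2 at 15680688 to 15684033 and C5 at 18270696 to 18361994.

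In all, 10 genes changed with all 6 libraries, 3 higher and 7 lower in KO, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment under 0.05. An unadjusted p under 0.05 was found for 2092 genes, against 923 expected if no gene differed. Lower with Lcn2 and C5 were Slc26a4 (the anion exchanger pendrin; chromosome 6, 48107575 to 48153762), from 9.45 ± 1.56 to 1.75 ± 0.206 CPM, Aoc1 (diamine oxidase, which degrades histamine; chromosome 4, 77812260 to 77831846), from 44.7 ± 2.48 to 15.2 ± 1.90 CPM, and Amigo2 (a neuronal-type adhesion protein; chromosome 7, 128391493 to 128394589), from 272 ± 16.2 to 107 ± 5.45 CPM. Their log2 fold changes were -2.43 (SE 0.22, adjusted p = 0.0269), -1.56 (SE 0.13, adjusted p = 0.0158) and -1.34 (SE 0.10, adjusted p = 0.00855). Ndufa10l1 (chromosome 6, 59879819 to 59881252) was lower with a log2 fold change of -2.58 (SE 0.26, adjusted p = 0.0349). LOC103691939 (chromosome 3, 143138360 to 143139773), which the naming rule leaves out and which was named after its values were seen, was lower by -1.76 (SE 0.12, adjusted p = 0.00647).

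Higher in KO were Lilrb3 (an inhibitory leukocyte immunoglobulin-like receptor; chromosome 1, 69928948 to 69939461), from 0.448 ± 0.170 to 4.60 ± 0.257 CPM, Plpp4 (a phospholipid phosphatase; chromosome 1, 183829794 to 183959319), from 2.29 ± 0.256 to 9.94 ± 1.67 CPM, and Acat2l1 (chromosome 1, 47803822 to 47829012), from 3.55 ± 0.443 to 11.7 ± 0.295 CPM (SD, n = 3 each). Their log2 fold changes were 3.33 (SE 0.32), 2.11 (SE 0.21) and 1.72 (SE 0.17), each with an adjusted p of 0.0349. Ndufa10l1, Acat2l1, Lilrb3 and LOC103691939 belong to families with similar copies, whose reads the counting could split, and their values are uncertain for that reason. When 1 KO library was left out, 1 or 2 genes passed the test.

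**Figure D3:**
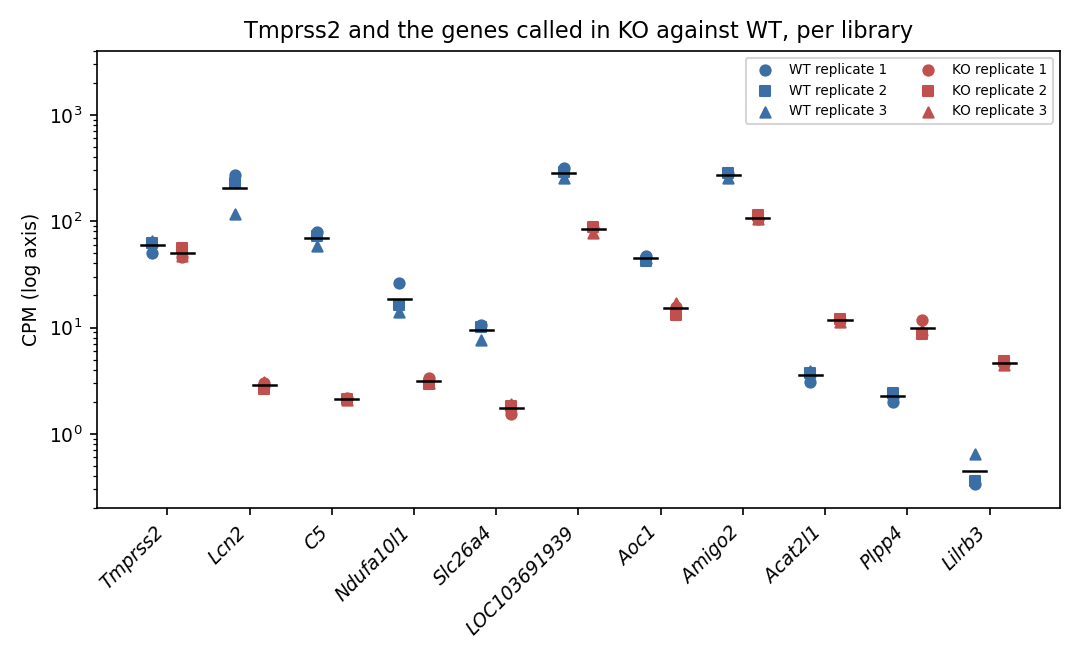
CPM on a log axis of Tmprss2 and the 10 genes past the threshold in each library; colour marks genotype, symbol marks replicate and the black bar is the group mean. The 3 KO libraries lie at 2.65 to 3.06 CPM for Lcn2 and at 2.07 to 2.17 CPM for C5, while Tmprss2 overlaps between genotypes.

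Leaving out each library in turn was planned, but the fit without WT replicate 1 was singled out after that library was seen to stand apart. In the fit without WT replicate 1, 758 genes changed, 314 higher and 444 lower, and the 10 genes above were all among them. Leaving out any other library gave 1 to 7 changed genes. Of the 758 genes, 754 were tested in both fits, and 749 of these had the same sign with all 6 libraries. This agreement was largely built in, since the fit with all 6 contains every library of the fit without WT replicate 1. Among the genes with the smallest p in that fit were Prf1, which rose by 0.97 on the log2 scale (SE 0.07, adjusted p = 7.55e-05), Tbx21, the T-bet transcription factor of NK and Th1 cells, which rose by 1.13 (SE 0.10), and Il2rb, an interleukin 2 and 15 receptor chain, which rose by 0.84 (SE 0.08). Larger rises were those of Nr1d1, the clock repressor REV-ERBα, by 2.13 (SE 0.29, adjusted p = 0.00399), Mc2r, the ACTH receptor, by 3.23 (SE 0.46), and the growth factor gene Bmp3 by 1.87 (SE 0.22). Akr1b8, Ak1 and Arhgef15 rose by 1.80, 1.35 and 0.71, and Tm4sf4 and Syt16, both under 2 CPM in KO, by 3.82 and 3.27. Among the genes that fell were Pla2g2a, a secreted phospholipase A2, at -3.11 (SE 0.43), Spp1, osteopontin, at -2.87 (SE 0.47), Cd109, at -2.68 (SE 0.28), Ndnf, at -0.91 (SE 0.06), and Myh14, a nonmuscle myosin, at -0.78 (SE 0.05). Sv2c, Zpld1 and Grik4 fell from 1.10 to 1.85 CPM in WT to 0.132 to 0.296 CPM in KO. Only 2 WT libraries stand behind these values.

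Among genes that the naming rule allows, 11 further ones had the smallest p of those that did not pass with all 6 libraries. They were not called, and all 11 passed without WT replicate 1. Genes that the rule does not name were left out whatever their p. Areg, the EGF receptor ligand amphiregulin, had a log2 fold change of -1.95 (SE 0.24, edgeR adjusted p = 0.0867), Cd109 one of -3.14 (SE 0.42, adjusted p = 0.0919), and Dll1, a Notch ligand, one of -1.03 (SE 0.14, adjusted p = 0.0919). MGC108823 stood at -1.50, Rab42 at -1.41, Lrrc8a, a volume-regulated anion channel subunit, at -0.87, Myh14 at -0.85, Adamts12 at -0.81 and Naaa at -0.71. S1pr5, a sphingosine 1-phosphate receptor of NK cells, stood at 1.19 and Spn, the leukocyte sialoprotein CD43, at 0.79.

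Gene groups fixed before the data were examined showed 2 broad directions. Lists of lymphocytes were higher in KO, and lists of matrix, mesothelium, platelets and immediate early genes were lower. Of 59 lists tested with camera at a preset correlation of 0.01, 27 passed an adjusted p under 0.05: 13 of 29 gene lists, all lower, and 14 of 30 cell type lists, 5 higher and 9 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.541. With fry, a self-contained test, used here for a shared direction, 1 list passed. Without WT replicate 1 the preset test passed 25 lists, 21 of them shared with the first 27 and in the same direction. In that fit, too, none passed with an estimated correlation, where the lowest adjusted p was 0.497. At the preset correlation, splits of the 6 libraries that mix genotypes passed up to 15 gene lists and 14 cell type lists. A pass alone thus does not point to genotype.

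The extracellular matrix and fibrosis list had the smallest p at the preset correlation, though not with fry, where it did not pass (adjusted p 0.0944). Of its 36 tested members, 34 had a log2 fold change below 0, with a median of -0.56; 25 were lower adjusted over the list alone and 0 over all genes tested with edgeR, where 25 had an unadjusted p under 0.05. The list passed at an adjusted p of 1.31e-13, and at an adjusted p = 0.541 with an estimated correlation. Tnc, tenascin C, stood at 116 ± 1.80 CPM in WT and 74.2 ± 5.61 CPM in KO, Spp1 at 6.67 ± 3.61 and 0.955 ± 0.385 CPM, Loxl2, a collagen crosslinking enzyme, at 76.1 ± 14.9 and 48.3 ± 0.377 CPM, and Col6a2 at 810 ± 99.1 and 556 ± 36.6 CPM (SD, n = 3 each). The median was -0.40 without WT replicate 1, with 22 members lower over all genes and 27 adjusted over the list alone. WT replicate 1 was itself higher than the other 5 libraries for this list, by a median of 0.68 on the log2 scale. The fibroblast list, which shares Col1a1, Col1a2, Col3a1, Col14a1, Dcn and Lum with the matrix list, was lower too. It had 12 of 15 members below 0, a median of -0.36 (-0.17 without WT replicate 1) and 4 lower adjusted over the list alone. It passed at 0.00366 (adjusted p = 0.541 with an estimated correlation), but is not fully separate from the matrix list.

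All 11 mesothelium markers were below 0, with a median of -0.72. The list passed at 2.11e-08, with an adjusted p = 0.541 with an estimated correlation; 9 members were lower adjusted over the list alone and 0 over all genes tested with edgeR (9 at an unadjusted p under 0.05). Upk3b, a uroplakin of the pleural lining, stood at 46.0 ± 2.62 CPM in WT and 24.4 ± 4.81 CPM in KO, Lrrn4 at 36.5 ± 4.71 and 18.4 ± 3.30 CPM, Bnc1 at 5.34 ± 1.66 and 1.79 ± 0.349 CPM, and Rspo1 at 29.3 ± 2.79 and 17.9 ± 2.59 CPM. The median was -0.86 without WT replicate 1, and 9 of the 11 passed over all genes.

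Lymphocyte markers were higher. All 16 tested NK cell markers had a log2 fold change above 0, with a median of 1.30, and the list passed at 1.94e-06, with an adjusted p = 0.541 with an estimated correlation. With all 6 libraries 0 of them passed in edgeR over all genes, 9 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Klrb1a, an NK receptor, stood at 5.83 ± 3.48 CPM in WT and 16.5 ± 1.84 CPM in KO, Eomes, a transcription factor of NK cells, at 2.22 ± 1.64 and 8.20 ± 1.48 CPM, and the granule gene Nkg7 at 7.93 ± 4.75 and 19.2 ± 1.07 CPM (SD, n = 3 each). WT replicate 1 lay below the other 5 libraries for this list by a median of -2.85. Without it the median was 0.88, 15 of 16 members were above 0, 10 passed over all genes and 14 adjusted over the list alone, and the list was the one that passed fry, with an adjusted p of 0.0215.

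The B cell list had a median of 0.75, with 12 of 14 members above 0 and 8 higher adjusted over the list alone. It passed at 1.03e-05, with an adjusted p = 0.541 with an estimated correlation. Cd79a, a B cell receptor subunit, stood at 24.9 ± 6.06 CPM in WT and 41.5 ± 5.33 CPM in KO, and Fcer2, the low-affinity IgE receptor, at 3.86 ± 1.72 and 9.33 ± 1.13 CPM; Pax5 and Cd22 had log2 fold changes of 1.02 and 0.69. The T cell list had a median of 0.74, with 15 of 16 members above 0 and 1, Cd8a, higher adjusted over the list alone. It passed at 0.000378, with an adjusted p = 0.541 with an estimated correlation. Cd8a stood at 16.5 ± 5.58 CPM in WT and 35.9 ± 2.37 CPM in KO, and Lat, Cd8b and Lck had log2 fold changes of 0.99, 0.87 and 0.86. WT replicate 1 lay below the other 5 libraries by a median of -0.99 for the B cell list and -1.38 for the T cell list. Without it the medians were 0.57 and 0.40, and 6 and 2 members passed over all genes. In the T cell list these were Cd8a and Lat (edgeR adjusted p 0.0020 and 0.0296), while Cd8b and Lck did not pass (0.163 and 0.148). Bulk counts do not show which cells carried these transcripts, so a rise of T cells themselves was not separated from the NK cell rise.

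The plasma cell list passed at 0.032, with a median of 0.29 and an adjusted p = 0.541 with an estimated correlation. The call was lost without WT replicate 2 (adjusted p 0.0503), without WT replicate 3 (0.186) and with sample quality weights (0.0543). It was also lost with protein-coding genes alone (0.2), but that setting leaves out Igha and Jchain, the leading members of the list. Its 13 members did not move as one: 9 were above 0 and 4 below, and 4 were higher adjusted over the list alone. Jchain, which joins IgA and IgM multimers, stood at 37.8 ± 6.55 CPM in WT and 88.3 ± 15.3 CPM in KO, and Igha, the IgA heavy chain, at 121 ± 39.1 and 309 ± 58.1 CPM; Pou2af1 and Mzb1 had log2 fold changes of 0.56 and 0.64. The median was 0.54 without WT replicate 1, and 4 members rose over all genes. The ciliated cell list, with a median of 0.47, passed at 0.00366 and at an adjusted p = 0.541 with an estimated correlation; 12 of 14 members were above 0, and without WT replicate 1 the median was 0.20.

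The platelet and erythroid lists passed as lower, while the neutrophil list and the eosinophil and basophil list did not pass camera with all 6 libraries (adjusted p 0.714 and 0.946). The megakaryocyte and platelet list had a median of -0.59, with 11 of 12 members below 0 and 4 lower adjusted over the list alone. It passed at 0.000189 and was the single list past fry with all 6 libraries, at an adjusted p of 0.0452, with an adjusted p = 0.541 with an estimated correlation. Tubb1, the platelet tubulin, stood at 4.58 ± 1.27 CPM in WT and 1.25 ± 0.198 CPM in KO, Treml1 at 2.26 ± 0.348 and 0.563 ± 0.124 CPM, and Itga2b and Pf4 had log2 fold changes of -1.02 and -0.97. The erythroid list had a median of -0.93, with 14 of 15 members below 0, and passed at 0.00387 (adjusted p = 0.541 with an estimated correlation), but not without WT replicate 3 (adjusted p 0.106). With all 6 libraries 0 erythroid members passed in edgeR over all genes, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Hba-a1, an alpha globin, stood at 431, 1307 and 1447 CPM in WT replicates 1 to 3 and at 772, 544 and 296 CPM in KO replicates 1 to 3. Hbb-bs, Slc4a1 and Bpgm had log2 fold changes of -2.07, -1.28 and -0.36. Hbb-bs varied within KO, at 11.1, 3.37 and 1.21 CPM in replicates 1 to 3, and its log2 fold change ran from -3.26 to -1.60 over the alternatives. The platelet and erythroid medians were -0.58 and -1.27 without WT replicate 1, and 2 and 5 members fell over all genes. WT replicate 1 lay above the other 5 libraries by a median of 0.62 for the platelet list and below them, at -0.80, for the erythroid list.

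The alveolar macrophage list had a median of -0.44, with 9 of 10 members below 0 and 6 lower adjusted over the list alone, and passed at 0.000229 (adjusted p = 0.541 with an estimated correlation). Krt79 stood at 43.8 ± 9.36 CPM in WT and 25.4 ± 3.05 CPM in KO, Trem2 at 8.01 ± 0.702 and 4.73 ± 0.423 CPM, and Fabp5 and Plet1 had log2 fold changes of -1.62 and -0.47. Fabp5 was highest in WT replicate 1, at 214 CPM, and stood at -0.99 without it. The surfactant and lipid handling list had a median of -0.41, with 20 of 21 members below 0, 2 lower adjusted over the list alone, and passed at 1.81e-06 (adjusted p = 0.541 with an estimated correlation). Its leading members were lipid genes rather than surfactant proteins: Scd, stearoyl-CoA desaturase, stood at 830, 416 and 294 CPM in WT replicates 1 to 3 and at a mean of 124 CPM in KO (log2 fold change -2.05, and -1.52 without WT replicate 1), Scd2 at 1660 ± 496 and 973 ± 104 CPM, and Ctsh, a protease that processes surfactant protein, had a log2 fold change of -0.41. Their medians were -0.46 and -0.21 without WT replicate 1, and 4 and 8 members passed over all genes, all lower. WT replicate 1 was higher than the other 5 libraries by a median of 0.52 for the first list and 0.71 for the second. The alveolar type 2 list, at a median of -0.41, passed at 0.00366 (adjusted p = 0.567 with an estimated correlation), and its median was -0.19 without WT replicate 1. It shares most of its genes with the surfactant list, so it is not a separate result.

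Among pathway lists, the immediate early genes, which respond within minutes to stimulation or tissue handling, had a median of -0.50, with 24 of 25 below 0 and 2 lower adjusted over the list alone. They passed at 2.60e-07, with an adjusted p = 0.541 with an estimated correlation. Dusp1 stood at 221 ± 63.3 CPM in WT and 100 ± 4.33 CPM in KO, Atf3 at 32.8 ± 13.4 and 11.9 ± 2.27 CPM, and Junb and Jund had log2 fold changes of -0.54 and -0.65. The glucocorticoid response list (median -0.37, 14 of 17 below 0) passed at 0.000426 (adjusted p = 0.541 with an estimated correlation), with Lcn2 as the member that fell over all genes and 5 lower adjusted over the list alone; Mt1 and Sgk1 had log2 fold changes of -1.01 and -0.68. The complement list (median -0.36, 19 of 26 below 0) passed at 0.000438 (adjusted p = 0.541 with an estimated correlation), with C5 as the member that fell over all genes and 3 lower adjusted over the list alone. C4a stood at 1897 ± 95.7 CPM in WT and 1173 ± 97.9 CPM in KO, and C2 and C1s had log2 fold changes of -0.72 and -0.59. The medians of these 3 lists were -0.34, -0.41 and -0.24 without WT replicate 1, and 3, 6 and 6 members fell over all genes, while 1 complement gene rose. WT replicate 1 was higher than the other 5 libraries by a median of 0.68 for the immediate early genes and 0.54 for the complement list.

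Cholesterol biosynthesis genes had a median of -0.22, with 21 of 22 below 0 and 1, Lss (lanosterol synthase), lower adjusted over the list alone at a log2 fold change of -0.72; Stard4, Dhcr7 and Cyp51 stood at -0.27, -0.90 and -0.41. The list passed at 0.000438 (adjusted p = 0.575 with an estimated correlation), and its median was -0.13 without WT replicate 1. The list of type II transmembrane serine proteases and matriptase partners, the family of Tmprss2, passed at 0.0382 with a median of -0.25 (adjusted p = 0.541 with an estimated correlation), but it did not pass without WT replicate 1 (0.13, with a median of -0.13) or in 5 of the other 17 settings. No member of it passed over all 18464 genes or over the list alone, and 1 of 15 had an unadjusted p under 0.05: Hpn, hepsin, at 15.5 ± 1.39 CPM in WT and 10.9 ± 1.01 CPM in KO. St14, matriptase, had a log2 fold change of -0.23 (-0.13 without WT replicate 1) and Tmprss12 one of -0.68. The viral entry list passed at 0.0133 with a median of -0.15 (adjusted p = 0.541 with an estimated correlation), and its median was -0.07 without WT replicate 1.

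**Figure D4:**
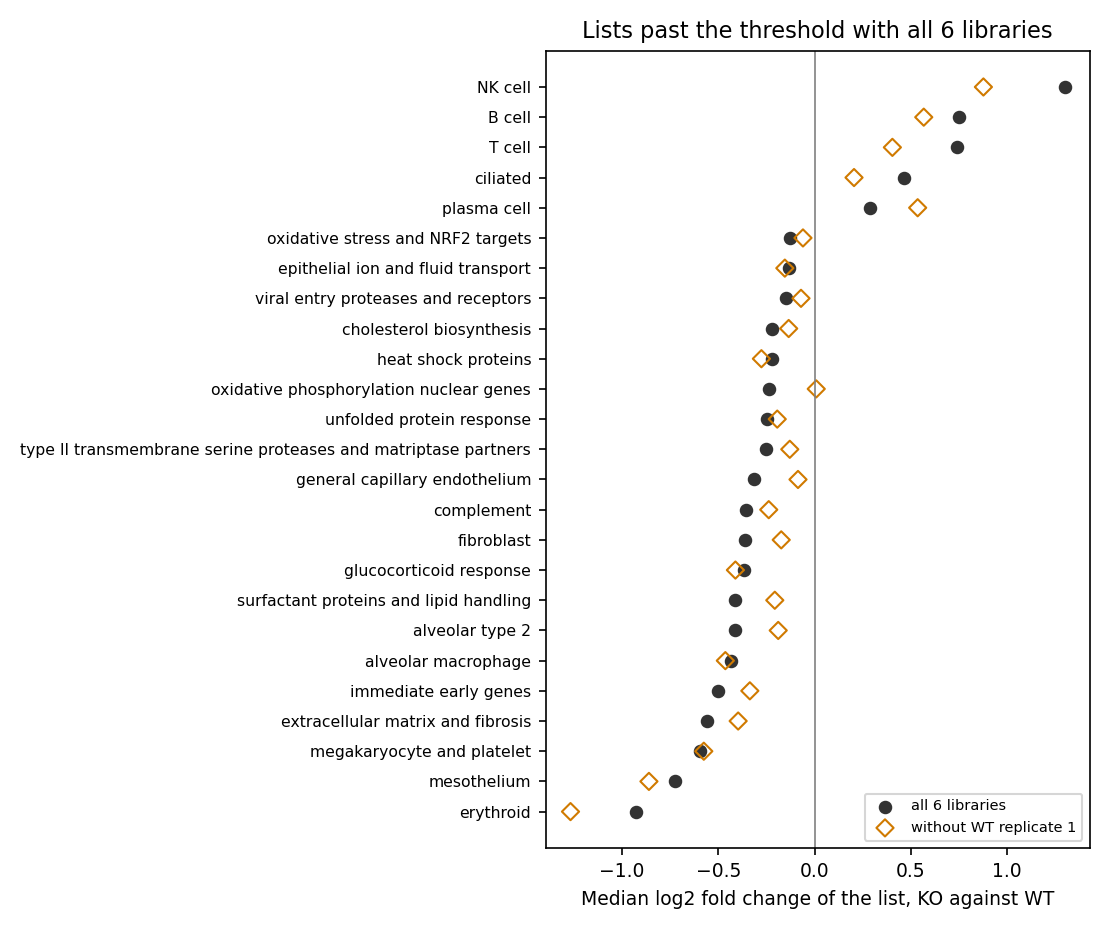
Median log2 fold change, KO against WT, of 25 of the 27 lists that passed the preset camera test, with all 6 libraries (filled circles) and without WT replicate 1 (open diamonds); the skeletal muscle and squamous epithelium lists are left off because their medians of -4.87 and -4.27 come from WT replicate 1. The NK cell list lies at 1.30 and 0.88 and the erythroid list at -0.93 and -1.27.

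Skeletal muscle and squamous markers followed WT replicate 1. The skeletal muscle list had a median of -4.87 and the squamous epithelium list one of -4.27; they passed at 0.00644 and 0.0446, each with an adjusted p = 0.665 with an estimated correlation. Without WT replicate 1 the medians were 0.00 and 0.05, at adjusted p-values of 0.955 and 0.944, and the squamous call was lost in 8 of 18 settings in all. Tnni2 stood at 446 CPM in WT replicate 1 and under 1 CPM in the others, and Casq1, Myh2, Krt14 and Aqp3 were highest in the same library, at 125, 118, 75.0 and 20.7 CPM. The cardiac muscle list did not pass with all 6 libraries (adjusted p = 0.296), and its median of 0.95 and mean of -0.66 differed in sign: Myl3 and Ckm, shared with skeletal muscle, were at 470 and 1792 CPM in WT replicate 1, while Myh7 and Ryr2 were highest in KO replicate 3, at 22.3 and 36.2 CPM. In the fit without WT replicate 1, 20 of 20 members were above 0, with a median of 0.76, a mean of 0.89 and an adjusted p of 0.0678 (0.786 with an estimated correlation). The list passed as higher without KO replicate 1 (adjusted p 0.00295), with the replicate block (0.00169) and with sample quality weights (0.00695), and was lower without KO replicate 3 (adjusted p 0.919).

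The authors' own comparison was deposited as a list of 192 genes, 88 higher and 104 lower in KO, and asks the same question. In the authors' deposited table the smallest absolute log2 fold change was 1 and the largest adjusted p 0.0479, and Tmprss2 was not among the genes listed. All 10 genes called here were listed there with the same sign, C5 at -5.05 and Lcn2 at -6.15 in the authors' deposited table. Of the 187 listed genes tested here, 187 had the same sign, and 137 were called without WT replicate 1. That table was made from the same counts, so these agreements were largely built in and add no separate evidence.

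Genes near Tmprss2 were examined because alleles linked to an edited locus can differ between a line and its control. Within 5 Mb on either side, 0 of 54 tested genes passed in edgeR with all 6 libraries, 6 had an unadjusted p under 0.05, and the DESeq2 Wald test called 2. Elsewhere 10 of 18410 genes passed, so few that a count of 0 near Tmprss2 could not show a difference (Fisher's exact test, two-sided, p = 1). Without WT replicate 1, 3 of 55 passed against 755 of 18939 elsewhere (Fisher's exact test, p = 0.483): Cbr1, LOC102556347 and Morc3, named after their values were seen, at log2 fold changes of 1.22, -3.85 and 0.30.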

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

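Sample quality weights and DESeq2 on unfiltered genes were chosen after the results were seen; the other settings were not. The number of calls moved with the libraries and the test. Leaving out 1 library in turn gave 1 to 758 changed genes (0 to 314 higher, 1 to 444 lower), 1 to 137 shared with the authors' deposited table and 0 to 3 near Tmprss2; the top of each range is the fit without WT replicate 1. Without WT replicate 2, 2 genes passed and without WT replicate 3, 7; without KO replicates 1, 2 and 3, 1, 2 and 2 passed, and 1 of the 10 was kept in each, C5. The DESeq2 Wald test on the same genes called 501 (194 higher, 307 lower), 183 of them listed by the authors and 2 near Tmprss2; the 10 genes were kept, and the cause was not tested. With sample quality weights, limma-voom gave WT replicate 1 a weight of 0.0772 and called 1676 genes (778 higher, 898 lower), 174 listed by the authors and 6 near Tmprss2, and Tmprss2 passed at -0.31 (adjusted p 0.0458; range over all alternatives 0.0458 to 0.829, log2 fold changes -0.36 to -0.18). DESeq2 on unfiltered genes with an absolute log2 fold change of at least 1 called 192 (88 higher, 104 lower), and 192 of these are the authors' 192. RLE and upper-quartile scaling, the robust fit, both count filters and protein-coding genes kept the 10 calls; limma-voom kept 7, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) kept 8 and 9, the last with 11 lower. No scaling moved the median of all genes by over 0.1 on the log2 scale. Lists past the threshold fell from 13 gene lists and 14 cell type lists to 0 and 0 with an estimated correlation and to 0 and 1 with fry. Krt4, Myl3 and Ckm, which were past no threshold, reversed without WT replicate 1: leaving out 1 library gave -9.82 to 0.33, -9.51 to 0.40 and -6.37 to 0.74, and with quality weights Krt4 stood at 0.14 and Ckm at 0.27. The skeletal muscle list changed direction without WT replicate 1, the cardiac list without KO replicate 3, the interferon list without WT replicate 3 and the clock list with DESeq2.

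The replicate numbers gave no sign of pairing: the deviations of same-numbered WT and KO libraries correlated at -0.08, 0.03 and -0.08 across genes. Libraries with different numbers ran from -0.114 to 0.123. Each deviation was taken from its group mean, which WT replicate 1 moves, so these values cannot exclude pairing. With the replicate number as a block, 2 genes passed (0 higher, 2 lower), and both were listed by the authors. In simulated data with all 6 libraries 45% of 2-fold changes were recovered among genes with higher counts. A short list of calls thus does not exclude further changes of that size. The simulation held no library that stood apart, so it does not measure the recovery in the real data.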

Other observations

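Tests of the explanations below were chosen after the results were seen, except the comparison of NK with B and T cell medians and the counts over other splits of the libraries. Clock genes moved in both directions, and their list passed no camera test (adjusted p = 0.748, and 0.663 without WT replicate 1). With fry run for changes in either direction, the list had an adjusted p of 0.00231 (0.00387 without WT replicate 1). That version passed 14 of 59 lists with all 6 libraries and 39 without WT replicate 1, so it does not single out the clock. Adjusted over the list alone, 4 of its 19 members were higher and 3 lower in KO. Nr1d1 had a log2 fold change of 2.00 (SE 0.32) and Nr1d2 stood at 26.8 ± 8.52 CPM in WT and 59.9 ± 6.76 CPM in KO, while Bhlhe41 stood at 23.1 ± 1.14 and 15.8 ± 1.09 CPM and Cry1 at 30.1 ± 4.94 and 18.8 ± 2.29 CPM (SD, n = 3 each). None of these passed over all genes with all 6 libraries; without WT replicate 1 all 4 passed, at log2 fold changes of 2.13, 0.94, -0.56 and -0.53. The hour at which tissue was taken is not given in the sources used here.

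Without WT replicate 1, 13 of 105 V segments were higher and 1 lower by edgeR. Segments of immunoglobulin and T cell receptor genes were not separated in this count. They were not a fixed list and were not tested as a group. The type I interferon list passed without WT replicate 1 (adjusted p = 0.00729; 0.773 with an estimated correlation; 29 of 32 members above 0) and not with all 6 libraries (adjusted p = 0.126); of the 18 settings it passed in 3. Ifit1 split the KO animals, at 31.7, 0.662 and 22.1 CPM in KO replicates 1 to 3 against at most 1.27 CPM in WT, and did not pass (adjusted p = 0.274). Rsad2 and Zbp1 had log2 fold changes of 0.41 and 0.61, and Ifitm3 one of -0.32, with all 6 libraries.

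WT replicate 1 differed from the other 5 libraries in both directions. RNA of another tissue is a candidate source of the genes that were higher: the skeletal muscle list lay 6.46 above the other 5 libraries (median log2, 12 of 12 members higher) and the squamous epithelium list 5.59 above, and a piece of a tissue that holds both, such as rat oesophagus, would bring them together. Dilution of lung RNA by such tissue is argued against as the source of the genes that were lower, since it would lower all lung cell types alike, and the NK cell median lay -3.54 from the alveolar type 2 median (permutation p = 0.00032 over 100000 resamples, 16 and 11 genes, which are not independent). A trend on gene length removed 0.992% of the spread between this library and the other WT libraries, which argues against length bias. Lists other than NK cells were lower in this library too, among them the T cell, neutrophil, B cell and erythroid lists, at medians of -1.38, -1.30, -0.99 and -0.80. The megakaryocyte and platelet list and the interstitial macrophage and monocyte list were higher, at 0.62 and 0.60. A difference of this animal or of the lung region sampled stays open and was not tested.

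C5 and Lcn2 were nearly lost together and lie 2.59 Mb apart on chromosome 3. A deletion that spans both is argued against: the 44 tested genes between them had a median log2 fold change of -0.11, from -1.53 to 1.62. Alleles linked to Tmprss2 are argued against too, since 0 of the 2 genes lie on its chromosome. A stretch of chromosome 3 that differs between the KO line and the WT rats may account for the pair: without WT replicate 1, 14 of 180 other genes within 5 Mb passed (7.78%, against 3.94% elsewhere; Fisher's exact test, p = 0.0186), among them Ak1 at 1.35, Hmcn2 at -1.41 and Phyhd1 at -0.73, named after their values were seen. Of 93 windows of 180 genes along the genome, 5 held at least 14 such genes, and a separate regulation of the 2 genes by genotype stays open.

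Lymphocyte lists were higher and the erythroid list lower in KO at the preset correlation (adjusted p = 0.541 with an estimated correlation for each). More blood in the KO lungs is argued against for the comparison with WT replicates 2 and 3. There the erythroid median was -1.27, and it would rise with blood. With all 6 libraries the median was -0.93, but 0 members passed adjusted over the list alone, and Hba-a1 overlapped between genotypes. The list was lower in all 18 settings, which share libraries, but did not pass without WT replicate 3 (camera adjusted p 0.106). WT replicate 1 alone is argued against, because the NK cell median was still 0.88 (log2) without it. Lymph node tissue in the KO samples could not be excluded. The fixed thymus and lymphoid stroma list had a median of 0.05 with all 6 libraries and did not pass (camera adjusted p 0.939). Without WT replicate 1 its median was 0.30, with 7 of 8 members above 0, and it did not pass either (camera adjusted p 0.421). The NK cell median exceeded the B cell median by 0.31 (permutation p = 0.078) and the T cell median by 0.47 (permutation p = 0.00015). These permutations shuffle genes, which are not independent, and do not measure the spread between animals. Lymph node tissue and a larger lymphocyte share in the lung thus cannot be told apart. A larger NK and lymphocyte share in lungs of the edited line, or in these 3 animals, stays open and was not tested.

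The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 10 genes, the highest other split 0, and 1 split reached the real count. It gave 10 genes shared with the authors' deposited table against 0 at most elsewhere, reached by 1 split, but that table was made from the same libraries under the real split, so this count says nothing about chance. For gene lists the real value was 13 and the highest other 15, with 2 splits at least as large; for cell type lists these were 14, 14 and 2. For genes near Tmprss2 the real value was 0, the highest other 0, and 10 splits gave as many, so this count cannot part the splits. Without WT replicate 1, the real split of 5 libraries called 758 genes and the highest of the other 9 called 2. For gene lists the real value there was 14 and the highest other 10, and for cell type lists 11 and 10. Passing lists at the preset correlation were thus common in splits that mix genotypes.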
